A study of Homo sapiens with 18 samples.

How the data were processed

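Poly(A)-selected RNA was sequenced from 18 libraries of THP-1, a human monocytic leukaemia cell line that carries the MLL-AF9 fusion. The first experiment held 12 libraries, 4 each of the parental line (wt) and of derivatives named PHF8 and F279S after the form of PHF8 they carry. The second held 6 libraries, 2 each of derivatives named ERAA, ERDD and ERPHF8, harvested on day 3. Per the labels' protocols, cells were kept in DMEM with fetal bovine serum, and 100 nM 4-hydroxytamoxifen (4-OHT) was used to induce the PHF8AA and PHF8DD forms. RNA was taken up with RNeasy columns and libraries were made with NEBNext Ultra II reagents and run on a NextSeq instrument. The labels give 4-OHT for the ERAA and ERDD libraries and name no treatment for ERPHF8, so each comparison with ERPHF8 is also a comparison with and without that tag. Each library was placed in its group by its title and genotype label, and 0 samples were left unassigned.

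For each library, the authors deposited a table of RPKM values for 19784 genes, together with each gene's hg38 coordinates. Per the submitters' processing notes, STAR 2.7.0c, SAMtools 1.9 and DESeq2 were used with hg38; the counting tool, its strand setting and the annotation release are not given in the sources used here. The values themselves showed how they had been made. In each library, every deposited RPKM value multiplied by the gene's span was a whole multiple of 1 step, within 0.001 reads for 100% of the values, and that step gave a whole-number library total. Whole reads per gene and the depth of each library could therefore be recovered. The span used was the full distance from gene start to gene end, introns included. In 1626 pairs of genes in which 1 lies inside the other, the outer gene held at least as many reads as the inner one in 100% of 15040 tests. Reads had thus been counted over the whole span, without regard to strand, and in every gene they overlapped. Reads summed over genes came to between 100.1 and 104.6% of the library total. In all, 6569 genes overlap another gene of the table and share reads with it, and 13215 do not. There were 0 genes of the mitochondrial genome, 21 names stood on more than 1 line (42 lines), and 18186 of the names (91.9%) were known to the GENCODE v29 and RefSeq name tables used here.

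The tests had been planned for counts. Because the deposited unit was RPKM, the test named beforehand for such values was used instead. RPKM was multiplied by the span in kilobases to give CPM, the reads of a gene per 1e6 reads of its library, so that the deposited scaling by library total was kept, and limma (version 3.58.1, R 4.3.3, data.table version 1.17.8) was fitted to log2(CPM + 0.5) with an intensity-dependent prior variance. Fold changes are on this log2(CPM + 0.5) scale, which understates the change of genes near or below 1 CPM. Genes entered with at least 1 CPM in at least 4 libraries of the first experiment (13683 genes) or at least 2 of the second (13831 genes). All 12 libraries of the first experiment were fitted together, as were all 6 of the second, with the group as the only term. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called changed. Means are given with the SD over libraries and log2 fold changes with their standard error (SE).

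The comparisons, the 19 gene lists, the main test and most alternatives were fixed before the data were examined. Of the lists, 17 were tested. The interferon genes themselves were too low to test and the mitochondrially encoded mRNAs had 0 genes in the tables. Lists were tested with limma's camera at a preset correlation of 0.01 on log2(CPM + 0.5), and p was adjusted over the lists within a comparison. With a correlation estimated from the data, the interferon-stimulated list was called in each of the 3 comparisons among the ER lines. No other list was then called in any comparison of groups. For those comparisons the correlation was estimated from the main fit, which leaves the library pairs out. In the first experiment, differences between the pairs therefore enter it, so a list not called this way is not shown to be unchanged. Tests of differences between the library pairs, described further below, called other lists too. The fry test, which asks whether the genes of a list move one way on balance, was run beside it. Named genes were chosen by a fixed rule: PHF8 in every comparison; the 8 largest rises and 8 largest falls of PHF8 against wt, PHF8 against F279S and ERDD against ERAA, and the 4 largest each way of the rest, among changed genes whose higher group averaged at least 1 CPM and whose groups did not overlap; and up to 4 members of each list described, by smallest p. A few genes that this rule selects are not reported here. Any other gene was chosen after its values were seen, which is said where it appears. Gene coordinates are 1-based, on hg38, as deposited.

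Library totals ranged from 18.2 to 51.5 M reads: 18.2 to 24.3 M in libraries 1 and 2 of the first experiment, 20.8 to 51.5 M in libraries 3 and 4, and 40.6 to 41.3 M in the ER lines. A count of 0 reads allows up to 3 reads, which is 0.0582 to 0.164 CPM depending on the library. Such floors cover counting error only. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. In a chi-square comparison of reads per gene, libraries 1 and 2 or 3 and 4 of a line differed by 1.95 to 11.8 per gene, where sampling noise alone gives about 1, and libraries of different pairs by 26.6 to 75.0. The libraries of an ER line differed by 1.86 to 15.4. No pair was therefore taken for a single library deposited more than once. Replicate numbers are shared between groups. Same-numbered libraries of the first experiment deviated from their group means together, with correlations across genes of 0.484 to 0.908, mostly because libraries 1 and 2 stood apart from 3 and 4 in every line: the other number of the same pair gave 0.235 to 0.819, and 8 of the 12 comparisons matched their own number best. The labels do not say what sets the pairs apart. The numbers were therefore tried as pairing the libraries of the first experiment, while the main fit and its p-values leave the pairing out. Counts of genes in the first experiment are given with the number as a block where that changes them. Its counts of list members are given with the library pair as a factor instead. Its counts of genes and several list medians are also given for libraries 1 and 2 and libraries 3 and 4 alone. In the ER lines, with correlations of -0.34 to 0.10, the numbers were not treated as pairs.

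The fit was tested on simulated reads drawn from the real means and library sizes with known changes. For PHF8 against wt (13685 genes) it recovered 26.2% of genes changed 1.25-fold, 56.7% of those changed 1.5-fold and 85.9% of those changed 2-fold, with 0 false calls. With the pair of libraries as a block these shares were 89.2, 95.5 and 100%, and 7.46% of the calls were false. For ERDD against ERAA (13725 genes) they were 77.3, 95.4 and 100%, with 5.29% false. The simulated genes shared 1 overdispersion, taken from libraries of the same line, and each change was the same in both pairs of libraries. In the real data the change of 4179 genes in PHF8 against wt differed between the pairs. The simulated rates therefore need not hold for the real libraries.

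The alternatives tried were median-ratio and TMM scaling (TMM factors computed from the values), no low-expression filter, a mean of at least 5 CPM, the replicate number or the library pair as a factor, each pair alone, the 2 compared groups alone, a 2-fold threshold, and each library left out in turn. Alternatives added after the data were seen were pseudocounts of 0.1 and 2 CPM, log2(RPKM + 0.1), voom on the recovered reads, pairs of libraries averaged, only genes overlapping no other, the removal of trends on GC content and span, and a crossed pairing of ERAA and ERPHF8. DESeq2 was planned and not run, and voom on the recovered reads took its place. Scaling by library total alone, planned as an alternative, is what the deposited values already have. Correlations between comparisons that share the wt libraries were set beside 50 simulated pairs of unchanged groups. Permutation tests and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.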

Results

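RNA levels were measured in 18 poly(A) RNA sequencing libraries of THP-1, a human monocytic acute myeloid leukaemia line with the MLL-AF9 fusion. The series concerns epigenetic control of the type I interferon response and of self-renewal in this leukaemia, with PHF8 as the gene varied. PHF8 is a histone demethylase with a PHD finger and a JmjC catalytic domain, and F279S is known as a form without catalytic activity. The first experiment compared parental cells (wt), cells with added PHF8 and cells with F279S (n = 4 libraries each). The second compared lines named ERAA, ERDD and ERPHF8 on day 3 (n = 2 each). Their labels name the forms PHF8AA, PHF8DD and PHF8; the letters AA, DD and ER are not spelled out. Library totals were 19.4 to 42.3 M reads for wt, 19.7 to 50.3 M for PHF8, 18.2 to 51.5 M for F279S and 40.6 to 41.3 M for the ER lines. Of the genes listed, 13683 were tested in the first experiment and 13831 in the second.

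PHF8 RNA (chromosome X, 53936676 to 54048958, hg38) followed the labels in every line. It averaged 50.6 ± 3.99 CPM in wt (SD, n = 4), 2020 ± 89.6 CPM in the PHF8 line and 5381 ± 320 CPM in the F279S line. These means were 40-fold and 106-fold that of wt, and F279S held 2.66 times as much PHF8 RNA as the PHF8 line. In the ER lines it averaged 2150 ± 219 CPM in ERAA (SD, n = 2), 1109 ± 14.8 CPM in ERDD and 1906 ± 8.51 CPM in ERPHF8. ESR1 encodes the oestrogen receptor, whose ligand-binding domain is commonly fused to proteins to make them respond to 4-OHT. It stood at 261 ± 19.9 CPM in ERAA, 125 ± 1.33 in ERDD and 230 ± 0.614 in ERPHF8. It was at 0.20 to 1.35 CPM in the libraries of the first experiment. ERAA had 1.94 times the PHF8 RNA and 2.08 times the ESR1 RNA of ERDD. The ratio of ESR1 to PHF8 was 0.113 to 0.124 in all 6 ER libraries. Reads of the added and of the resident PHF8 gene are not told apart here.

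**Figure D1:**
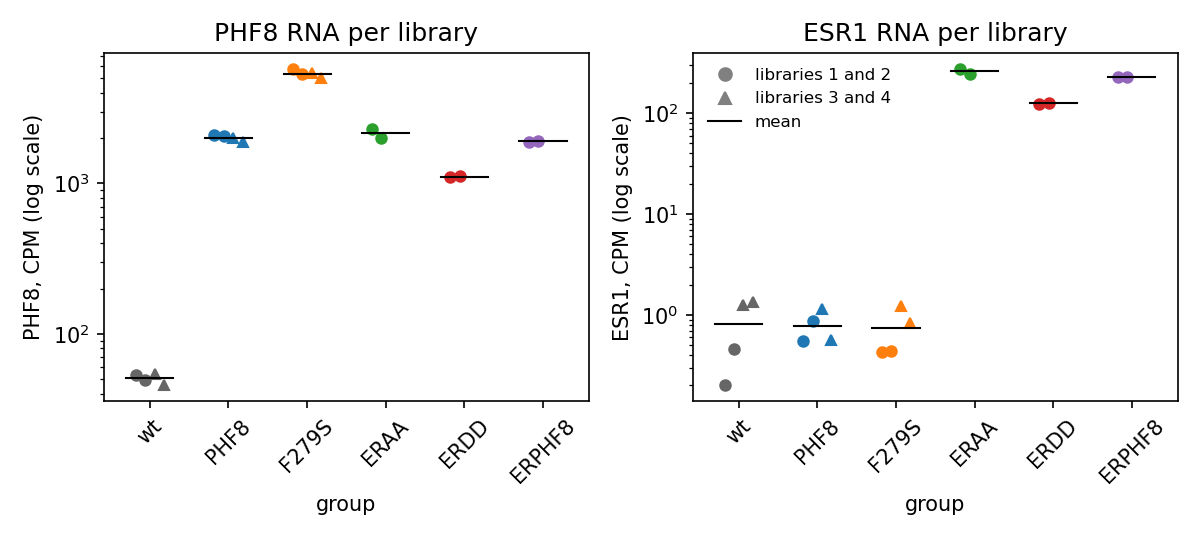
PHF8 and ESR1 levels in CPM, on log axes, in each of the 18 libraries; bars are group means, circles are libraries 1 and 2 and triangles libraries 3 and 4. PHF8 averaged 50.6 CPM in wt and between 1109 and 5381 CPM in the other lines, and ESR1 averaged 125 to 261 CPM in the ER lines and was at most 1.35 CPM in any other library.

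The comparison of PHF8 with wt asked what added PHF8 does to the cells' transcripts. The largest rises began at very low levels. PGR, the progesterone receptor (chromosome 11, 101029624 to 101130524), rose from 0.600 ± 0.247 to 7.88 ± 1.06 CPM, a log2 change of 2.95 ± 0.19 (SE, adjusted p = 2.0e-06). GFRA2, a receptor for GDNF-family ligands (chromosome 8, 21690403 to 21812357), rose by 2.87 ± 0.27 (2.2e-05), and ADAM28, a metalloprotease (chromosome 8, 24294040 to 24359018), by 2.85 ± 0.32 (8.6e-05). MEOX2, a homeobox gene (2.48 ± 0.16), NCKAP1, a WAVE-complex subunit (2.46 ± 0.17), and NPY, neuropeptide Y (2.44 ± 0.21), rose as well. PNMA2 rose by 2.94 ± 0.47 (0.00089) but overlaps BNIP3L, so its reads are uncertain. Of the largest falls, FCER2, the low-affinity IgE receptor (chromosome 19, 7688758 to 7702146), went from 9.86 ± 6.87 to 0.786 ± 0.339 CPM, a log2 change of -2.76 ± 0.47 (0.0013). SERPINB2, the inhibitor of plasminogen activators (chromosome 18, 63871692 to 63903890), went from 147 ± 17.5 to 30.7 ± 0.864 CPM, a change of -2.23 ± 0.11 (2.5e-07); SERPINB10 beside it overlaps it and changed equally, so the pair is uncertain.

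Other large falls were ARAP3, a GTPase-activating protein (-2.08 ± 0.43), the Notch ligand DLL4 (-1.84 ± 0.15) and ANXA8 (-1.85 ± 0.39), an annexin with near-identical copies and hence uncertain. CR1, the complement receptor (-2.34 ± 0.67, adjusted p = 0.028), and SLC2A3, a glucose transporter (-2.02 ± 0.59, 0.030), also passed, but each lost its call when any 1 of PHF8 libraries 1 and 2 or wt libraries 3 and 4 was left out. Without each of those in turn, CR1 in PHF8 against wt stood at -2.19, -2.15, -1.88 and -1.93, and SLC2A3 in PHF8 against wt at -1.80, -1.79, -1.75 and -1.77. The libraries 1 and 2 and the libraries 3 and 4, taken alone, gave all the genes named above the same direction. The naming rule fixed that direction beforehand, since it took only genes whose groups did not overlap. In the pairs PGR changed by 2.67 and 3.22, ADAM28 by 3.43 and 2.26, FCER2 by -2.13 and -3.39, and SERPINB2 by -2.13 and -2.34.

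In all, 2874 genes changed between PHF8 and wt, 1741 higher and 1133 lower (limma), and 450 of the 13683 changed at least 2-fold, 355 of them higher. With the replicate number as a block the count was 5670 (3066 higher, 2604 lower), and with each pair averaged and the pair as a block 1775, which included 1597 of the 2874. Libraries 1 and 2 alone gave 7025 and libraries 3 and 4 alone 5833; of the 3550 genes called in both, 2990 had the same direction and 560 opposite ones. Genes called higher had a median transcript GC content of 44.5% and a median span of 58.5 kb, those called lower 54.8% and 27.6 kb, and the rest 48.9% and 31.7 kb.

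Interferon-stimulated genes, the list of transcripts that type I interferon induces, rose in part in the PHF8 line: 22 of 45 members were higher and 1 lower. Counts adjusted over the list alone are given from here on where they differ, and here were 23 and 2. OAS1, a sensor of double-stranded RNA, went from 5.76 ± 1.23 to 19.4 ± 0.83 CPM (log2 change 1.69 ± 0.16, adjusted p = 2.1e-05), and RSAD2, the antiviral enzyme viperin, from 6.37 ± 0.705 to 14.6 ± 1.83 CPM (1.13 ± 0.11, 2.5e-05). PLSCR1 rose by 0.51 ± 0.05 and MX2 by 0.45 ± 0.06. The median over the list was 0.39, with adjusted p = 3.3e-06 by camera and adjusted p = 0.62 with an estimated correlation. That correlation was estimated with the library pairs left out of the fit. Libraries 1 and 2 alone gave a median of 0.46 and libraries 3 and 4 alone 0.39. Among 24 sensing and signalling genes of the pathway, 2 rose and 4 fell (median -0.06, adjusted p = 0.60). The DNA sensor IFI16 rose from 13.4 ± 0.501 to 35.9 ± 1.67 CPM (1.39 ± 0.10) and DDX58, which encodes the RNA sensor RIG-I, by 0.83 ± 0.08. The transcription factor IRF5 changed by -0.42 ± 0.05. The interferon genes themselves were at most 0.145 CPM, the highest being IFNA4, where a count of 0 allows up to 0.0582 to 0.164 CPM, and differences in them were not tested. IFNA4, named after its values were seen, had 11 reads summed over the PHF8 libraries, 6 over F279S and 2 over wt.

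Genes of the monocyte and macrophage list went both ways, with 7 of 37 higher and 9 lower (9 and 11 adjusted over the list alone; median -0.10, adjusted p = 0.48). The median was 0.11 in libraries 1 and 2 alone and -0.23 in libraries 3 and 4. LYZ, lysozyme, went from 855 ± 149 to 252 ± 93.1 CPM (-1.82 ± 0.22, 0.00014). S100A8 and S100A9, the subunits of calprotectin, went from 76.7 ± 26.5 to 23.5 ± 1.14 CPM (-1.62 ± 0.21) and from 255 ± 97.3 to 79.0 ± 10.8 CPM (-1.61 ± 0.23). MMP9, a secreted gelatinase, rose by 1.53 ± 0.16. Of the MLL-fusion self-renewal genes, 9 of 26 rose and 2 fell (median 0.16, 0.13; 0.22 and 0.04 in the pairs alone). ZNF521, a haematopoietic zinc-finger factor, rose from 131 ± 7.93 to 202 ± 5.11 CPM (0.63 ± 0.06, 1.9e-05). BMI1, a Polycomb protein, rose from 284 ± 59.1 to 512 ± 12.8 CPM (0.87 ± 0.13, 0.00063). KIT, the stem cell factor receptor, rose from 0.746 ± 0.119 to 3.50 ± 0.796 CPM (1.67 ± 0.16, 2.9e-05). Of the LSC17 stemness score, 9 of its genes were high enough to test and 1 rose, LAPTM4B (0.44 ± 0.08; list median 0.24, 0.48).

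Among NF-kB targets 2 of 21 rose and 6 fell (median -0.21, adjusted p = 0.13). The chemokine CCL5 went from 121 ± 33.4 to 43.4 ± 1.76 CPM (-1.43 ± 0.16), CCL2 changed by -1.06 ± 0.22 and CXCL8 by -0.67 ± 0.12. BIRC3, an inhibitor of apoptosis, rose by 1.18 ± 0.18. Antigen presentation genes split, 5 of 26 higher and 4 lower (5 and 5 adjusted over the list alone; -0.08, 0.54). The class II genes HLA-DRA (13.5 ± 5.69 to 44.8 ± 18.4 CPM, 1.69 ± 0.36), HLA-DPA1 (1.58 ± 0.30) and HLA-DMB (1.07 ± 0.23) rose. Tapasin, TAPBP, changed by -0.38 ± 0.07. Of 29 apoptosis genes 7 rose and 0 fell (0.23, 0.13), with CASP4 at 0.65 ± 0.06 and SESN1 at 0.80 ± 0.14. Of the 22 genes of the integrated stress response 4 rose and 1 fell (0.04, 0.48). PHGDH, the first enzyme of serine synthesis, went from 98.8 ± 1.44 to 210 ± 25.7 CPM (1.07 ± 0.08, 5.8e-06), and ATF3 and ASNS rose by 1.21 ± 0.15 and 0.98 ± 0.17.

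Of 19 histone demethylases, 4 were higher, PHF8 among them, and 2 lower (median 0.01, adjusted p = 0.86; 4 and 5 adjusted over the list alone). PHF2 was lower (-0.59 ± 0.06), and KDM1B and KDM7A were higher (0.63 ± 0.07 and 0.82 ± 0.18). Cell cycle genes had 4 of 33 higher, among them CDK1 (0.25 ± 0.06) and MCM7 (0.38 ± 0.09), and 1 lower, E2F1 (-0.26 ± 0.06; median 0.07, 0.48; 3 and 1 adjusted over the list alone). For ribosome biogenesis and MYC targets, 0 of 27 passed (0.01, 0.88), and the pairs of libraries gave medians of opposite sign, -0.26 and 0.28. The sterol genes also had 0 of 21 (0.06, 0.86), with 0.15 and -0.19 in the pairs. Heat shock and immediate early genes had 2 of 15 higher and 0 lower (0.04, 0.86), and 0 adjusted over the list alone. DUSP1 in PHF8 against wt (0.85 ± 0.25, 0.030) lost its call without 1 of 4 libraries, with 0.69 without PHF8 3. HSPB1 in PHF8 against wt (0.37 ± 0.12, 0.044) lost it without 1 of 6, with 0.27 without PHF8 2. Hypoxia genes had 1 of 20 lower, SLC2A3 (-0.11, 0.48), and 0 adjusted over the list alone. Granulocyte genes had 2 of 11 lower (-0.15, 0.48), among them FUT4 (-0.49 ± 0.10). Markers of other lineages had 2 of 8 higher (0.13, 0.48), NCAM1 (1.44 ± 0.24) and fetal haemoglobin HBG2 (0.99 ± 0.18), the latter with a near-identical copy. With the library pair as a factor, higher and lower members came to 26 and 3 for the interferon-stimulated list and 4 and 5 for sensing. They came to 11 and 13 for monocyte genes, 12 and 4 for MLL-fusion genes and 2 and 1 for other lineages. They came to 7 and 10 for antigen presentation, 4 and 9 for NF-kB, 4 and 0 for LSC17, 11 and 2 for cell cycle, and 13 and 3 for apoptosis. They were 7 and 3 for the stress response, 6 and 6 for demethylases, 2 and 6 for hypoxia and 2 and 5 for granulocytes. Heat shock and sterol genes had 3 and 2 each, and ribosome biogenesis 1 and 0.

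The F279S line, set against wt, held more PHF8 RNA than the PHF8 line, and 2 genes passed. They were PHF8 itself (log2 change 6.72 ± 0.07, adjusted p = 2.9e-14; 5.31 ± 0.07 in PHF8 against wt, 4.7e-13) and ACPP, prostatic acid phosphatase (chromosome 3, 132317367 to 132368298). ACPP, named after its values were seen, went from 14.3 ± 0.277 to 25 ± 1.74 CPM (0.79 ± 0.07, 0.00056) and stood at 37.5 ± 1.96 CPM in the PHF8 line. At an unadjusted p below 0.05 there were 871 genes, and voom also called 2. The count depended on how the library pairs were treated. With the replicate number as a block 298 genes were called (182 higher, 116 lower), but with each pair averaged and the pair as a block 1 was called. Libraries 1 and 2 alone gave 1918 and libraries 3 and 4 alone 12.

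Interferon-stimulated genes shifted together in F279S without any member passing: 0 of 45 were called (1 higher adjusted over the list alone), the median was 0.24, and camera gave adjusted p = 1.1e-15 against adjusted p = 0.21 with an estimated correlation. The shift lay in libraries 1 and 2, with a median of 0.43 (adjusted p = 1.1e-27), against 0.08 in libraries 3 and 4 (0.14). OAS1 was at 11.6 ± 2.32 CPM (0.95 ± 0.16, 0.11; 1.43 and 0.47 in the pairs) and TRIM22 at 6.50 ± 3.98 against 1.95 ± 0.217 CPM in wt (1.32 ± 0.36, 0.37; 2.19 and 0.45). The mean log2 level of the list was 4.08 in F279S libraries 1 and 2 and 3.65 and 3.66 in libraries 3 and 4, beside 3.50 to 3.61 in wt and 3.97 to 4.04 in PHF8.

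**Figure D2:**
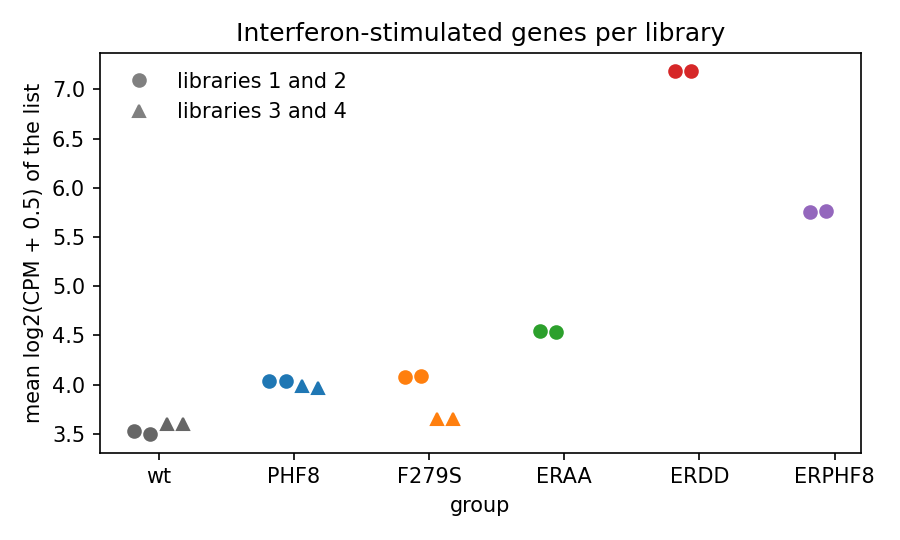
Mean log2(CPM + 0.5) of the 45 interferon-stimulated genes in each library; each point is 1 library, circles for libraries 1 and 2 and triangles for 3 and 4. The wt libraries lie between 3.50 and 3.61, F279S libraries 1 and 2 at 4.08, ERAA at 4.54 and 4.55, ERPHF8 at 5.76 and ERDD at 7.18.

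For the other lists in F279S against wt, 0 members passed over all genes except PHF8 among the demethylases (1 of 19; median -0.07, adjusted p = 0.67). Camera called 8 further lists, each lost with an estimated correlation. NF-kB targets had a median of 0.09 (0.022; adjusted p = 0.40 with an estimated correlation), where CCL3 stood at 1.03 ± 0.18 (0.13). Monocyte genes had 0.10 (0.0061; p = 0.61 with an estimated correlation), with CTSD at 0.40 ± 0.09 and S100A8 at -0.93 ± 0.21 (0.23 each). Cell cycle genes had 0.10 (0.0045; p = 0.52 with an estimated correlation) and the stress response 0.18 (0.0083; p = 0.52 with an estimated correlation). Heat shock genes had 0.16 (0.0082; p = 0.21 with an estimated correlation) and markers of other lineages 0.27 (0.0082; p = 0.47 with an estimated correlation). NKG7, a cytotoxic granule protein of the latter list, was at 0.63 ± 0.09 (0.066). MLL-fusion genes were at -0.04 (0.031; p = 0.21 with an estimated correlation) and granulocyte genes at -0.04 (0.047; p = 0.21 with an estimated correlation). Cathepsin G, CTSG, was at -0.58 ± 0.15. Within the pairs these medians were 0.10 and 0.03 for NF-kB, 0.17 and 0.05 for monocyte genes, 0.10 and 0.07 for cell cycle, and 0.22 and 0.12 for the stress response. They were 0.16 in both for heat shock, 0.48 and 0.11 for other lineages, -0.07 and -0.06 for MLL-fusion genes and -0.05 and -0.17 for granulocyte genes. Sensing genes (0.01, 0.53), antigen presentation (-0.02, 0.96), LSC17 (0.01, 0.65), ribosome biogenesis (-0.01, 0.96), apoptosis (0.02, 0.37), sterol genes (0.01, 0.88) and hypoxia genes (-0.12, 0.58) were not called, the last reaching 0.015 under the block. Adjusted over the list alone, 3 NF-kB targets, 3 monocyte genes and 1 gene of other lineages were higher, and 1 monocyte and 2 granulocyte genes lower. With the library pair as a factor 4 NF-kB targets, 5 monocyte, 3 interferon-stimulated and 2 heat shock genes passed as higher. So did 2 stress response genes, 2 other-lineage genes and 1 cell cycle gene. As lower passed 3 monocyte, 3 hypoxia and 2 granulocyte genes and 1 each of antigen presentation, MLL-fusion and stress response genes. With each pair averaged and the pair as a block, 1 gene was called in F279S against wt. It was PHF8 or ACPP, so all these members lost their call.

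PHF8 against F279S compared the active with the catalytically inactive form. Both this comparison and that with wt use the same PHF8 libraries, and many of the genes named there stood out here too. PGR rose by 2.72 ± 0.19 (adjusted p = 4.5e-06), GFRA2 by 2.64 ± 0.27, ADAM28 by 3.02 ± 0.32, NCKAP1 by 2.54 ± 0.17, MEOX2 by 2.33 ± 0.16 and PNMA2, with its uncertain reads, by 3.10 ± 0.47. ID3, an inhibitor of basic helix-loop-helix factors (chromosome 1, 23557918 to 23559794), rose from 3.76 ± 3.45 to 23.3 ± 10.9 CPM (2.85 ± 0.58, 0.0047). VCAN, the proteoglycan versican (chromosome 5, 83471465 to 83582303), rose from 99.2 ± 71.7 to 576 ± 377 CPM (2.61 ± 0.65, 0.015). Among the genes lower in the PHF8 line, CD209, the lectin DC-SIGN (chromosome 19, 7739994 to 7747564), was at 21.0 ± 3.26 against 91.9 ± 7.79 CPM (-2.11 ± 0.21, 3.6e-05). ANPEP, aminopeptidase N or CD13 (chromosome 15, 89784889 to 89815401), was at 43.5 ± 12.7 against 173 ± 12.9 CPM (-2.03 ± 0.21, 6.1e-05), and FCER2 differed by -3.29 ± 0.47 (0.00042).

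IL31RA, a cytokine receptor chain (-1.92 ± 0.41), CCL5 (-1.90 ± 0.16), SERPINB2 (-1.89 ± 0.11) and DCANP1, which overlaps TIFAB (-1.95 ± 0.47), were also lower in PHF8 than in F279S. CR1 in PHF8 against F279S (-2.14 ± 0.67, adjusted p = 0.043) lost its call when any 1 library of either line except F279S 2 was left out, with values from -2.33 without F279S 1 to -1.83 without F279S 3. PHF8 RNA itself was lower in the PHF8 line (-1.41 ± 0.07, 5.3e-07). In all 2750 genes differed, 1666 higher and 1084 lower, with 391 at least 2-fold. The count was 5620 (3179 higher, 2441 lower) with the replicate number as a block, 7357 in libraries 1 and 2 alone and 4867 in libraries 3 and 4 alone. With each pair averaged and the pair as a block it was 1594, which included 1400 of the 2750. Of 3270 genes called in both pairs, 2968 had the same direction. All the genes named as largest for this comparison kept their direction in both pairs of libraries. The naming rule fixed this beforehand, since it took only genes whose groups did not overlap.

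By list, NF-kB targets were lower in PHF8 than in F279S, 2 of 21 higher and 9 lower (2 and 10 adjusted over the list alone; median -0.35, adjusted p = 0.017; adjusted p = 0.49 with an estimated correlation; -0.39 and -0.35 in the pairs). They included TNF, at 28.7 ± 1.96 against 60.5 ± 8.34 CPM (-1.06 ± 0.18), and CXCL8 (-0.81 ± 0.12), while BIRC3 was higher (1.36 ± 0.18). MLL-fusion self-renewal genes were higher, 10 of 26 against 1 lower (10 and 2 adjusted over the list alone; 0.22, 0.038; p = 0.48 with an estimated correlation; 0.097 under the block; 0.27 and 0.12 in the pairs). KIT was at 1.92 ± 0.16, BMI1 at 1.08 ± 0.13 and ZNF521 at 0.76 ± 0.06. Monocyte genes were lower, 5 of 37 higher and 10 lower (5 and 13 adjusted over the list alone; -0.23, 0.038; p = 0.99 with an estimated correlation; 0.097 under the block; -0.23 and -0.24 in the pairs). LYZ was at -1.47 ± 0.22, CTSD, cathepsin D, at -0.77 ± 0.09 and the Fc receptor FCGR1A at -0.76 ± 0.11. Of the interferon-stimulated list 11 of 45 were higher and 1 lower (0.09, 0.36), among them RSAD2 (1.16 ± 0.11) and OAS1 (0.74 ± 0.16). Its median was -0.07 in libraries 1 and 2 and 0.30 in libraries 3 and 4 (0.0024).

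The remaining lists were not called between PHF8 and F279S. Sensing genes had 2 of 24 higher and 4 lower (-0.01, adjusted p = 0.61), again with IFI16 (1.08 ± 0.10) and DDX58 (0.72 ± 0.08) up. Antigen presentation had 5 of 26 higher and 2 lower (5 and 6 adjusted over the list alone; -0.09, 0.61), with HLA-DPA1 at 1.71 ± 0.30. LSC17 had 4 of 9 higher and 0 lower (4 and 1 adjusted over the list alone; 0.33, 0.38), with CDK6 at 0.67 ± 0.16 and SOCS2 at 0.48 ± 0.11. Apoptosis genes had 7 of 29 higher and 1 lower (0.21, 0.21), with CASP4 at 0.58 ± 0.06 and the survival gene BCL2A1 at -0.97 ± 0.16. The stress response had 5 of 22 higher and 1 lower (5 and 2 adjusted over the list alone; -0.06, 0.96), with PHGDH at 0.97 ± 0.08 and ASNS at 1.06 ± 0.17. Cell cycle had 3 of 33 higher and 2 lower (2 and 2 adjusted over the list alone; -0.01, 0.75) and demethylases 3 of 19 higher and 2 lower (0.09, 0.96). Granulocyte genes had 1 of 11 each way (2 and 1 adjusted over the list alone; 0.08, 0.96) and other lineages 2 of 8 each way (0.09, 0.96). Heat shock genes had 1 of 15 lower (0 adjusted over the list alone; -0.12, 0.51). Ribosome biogenesis (0.02, 0.96; -0.18 and 0.24 in the pairs), sterol (0.04, 0.96) and hypoxia genes (-0.01, 0.75) had 0 members called. With the library pair as a factor, higher and lower members came to 4 and 12 for NF-kB and 6 and 16 for monocyte genes. They came to 12 and 3 for MLL-fusion genes and 14 and 6 for the interferon-stimulated list. For sensing they were 4 and 6, for antigen presentation 6 and 11 and for apoptosis 12 and 5. They came to 6 and 10 for the stress response, 5 and 2 for LSC17, 4 and 5 for cell cycle, 5 and 3 for demethylases and 4 and 2 for granulocytes. They were 1 and 6 for heat shock, 5 and 1 for sterol, 1 and 3 for hypoxia and 2 and 0 for ribosome biogenesis.

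PHF8 against wt and F279S against wt share the wt libraries. Across genes, which are not independent replicates, their fold changes had a Pearson correlation of 0.289 and a Spearman correlation of 0.258. In 50 simulations of unchanged groups against those controls the Pearson correlation averaged 0.502. Changes found in PHF8 against wt alone lower the observed value, so these correlations do not tell whether the lines share a change. The observed covariance of 0.0194 exceeded the simulated mean of 0.00593 by 0.0135. PHF8 itself, raised in both lines by the design, entered the observed value, and no spread of the simulated values is given here. With the wt libraries split between the comparisons the correlation was 0.236 and 0.20. Each part held a wt library of both pairs, so deviations common to a pair stayed shared. PHF8 and ACPP, the 2 shared calls, compare with 0.254 for independent lists and 0 in the simulations. The design fixed the shared call of PHF8 beforehand, so ACPP alone bears on a shared change.

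ERDD against ERAA compared PHF8DD with PHF8AA, both under the 4-OHT tag. Of the 8 largest rises, 7 were interferon-stimulated genes. IFI27 (chromosome 14, 94104836 to 94116698) stood at 121 ± 3.41 CPM in ERDD and 1.41 ± 0.182 in ERAA (SD, n = 2; log2 change 6.0 ± 0.09, adjusted p = 5.4e-09). IFI44L (chromosome 1, 78619922 to 78646145) stood at 173 ± 2.97 and 2.46 ± 0.245 (5.88 ± 0.07, 1.8e-09). MX1, a dynamin-like GTPase that blocks influenza virus (chromosome 21, 41420304 to 41459214), stood at 460 ± 3.65 and 17.6 ± 0.0336 (4.67 ± 0.04, 3.9e-10). IFI44 rose by 4.36 ± 0.06, OAS3 by 3.99 ± 0.06, the ubiquitin-like ISG15 (chromosome 1, 1001138 to 1014541) by 3.95 ± 0.07 and IFIT1, whose span overlaps LIPA, by 4.24 ± 0.08. OTOF, otoferlin, which is not on the list, rose from 0.943 ± 0.3 to 20.3 ± 0.405 CPM (3.86 ± 0.14).

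All 45 interferon-stimulated genes were higher in ERDD than in ERAA and 0 lower, with a median of 2.35 (adjusted p = 1.1e-26; adjusted p = 0.016 with an estimated correlation). Of 28 sensing and signalling genes 15 rose and 7 fell (0.21, 0.067). IFI16 went from 57.1 ± 2.88 to 198 ± 0.149 CPM (1.79 ± 0.05), and DDX58, DHX58 and IFIH1, the RIG-I-like receptors, rose by 1.70 ± 0.05, 1.85 ± 0.06 and 1.67 ± 0.06. Antigen presentation divided, 7 of 26 higher and 12 lower (-0.18, 0.42). TAP1, TAP2 and PSMB9 of the class I pathway rose by 0.76 ± 0.04, 0.74 ± 0.05 and 0.78 ± 0.05. CD74, the class II invariant chain, went from 572 ± 41.8 to 289 ± 6.41 CPM (-0.98 ± 0.05). The interferon genes themselves were again near the floor, with 9 reads of IFNB1 summed over the ERDD libraries, 2 over ERAA and 3 over ERPHF8.

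Of the largest falls in ERDD, ASS1, argininosuccinate synthase (chromosome 9, 130444929 to 130501274), went from 473 ± 38.4 to 52.5 ± 2.29 CPM (-3.16 ± 0.06, adjusted p = 1.7e-08), and G0S2, an inhibitor of triglyceride lipase, from 34.5 ± 3.03 to 3.40 ± 0.193 CPM (-3.16 ± 0.08). STC2, stanniocalcin (-3.09 ± 0.06), INHBE, an inhibin subunit (-2.95 ± 0.10), and CHAC1, which degrades glutathione (-2.73 ± 0.06), are known targets of ATF4 signalling. AKR1C1 (-3.38 ± 0.07) and AKR1C2 (-3.25 ± 0.07), steroid-reducing enzymes, overlap each other, and SULF2 (-3.26 ± 0.05), an extracellular sulfatase, overlaps NCOA3, so these 3 are uncertain. In the stress response list 8 of 22 rose and 13 fell (median -0.75, 0.086). DDIT4 went from 385 ± 13.8 to 64.2 ± 0.532 CPM (-2.57 ± 0.04) and ASNS, asparagine synthetase, from 249 ± 2.58 to 45.4 ± 1.1 CPM (-2.44 ± 0.04). PSAT1, of serine synthesis, went from 599 ± 2.01 to 141 ± 1.77 CPM (-2.08 ± 0.04). Hypoxia genes had 5 of 21 higher and 13 lower (-0.30, 0.059), with VEGFA from 207 ± 11.6 to 34.2 ± 1.47 CPM (-2.58 ± 0.07) and the glycolytic ALDOC at -1.93 ± 0.05.

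Lists of cell cycle, ribosome biogenesis, sterol and heat shock genes were higher in ERDD. Of 33 cell cycle genes 32 rose and 0 fell (median 0.79, adjusted p = 2.1e-13; adjusted p = 0.092 with an estimated correlation). The replication helicase subunit MCM3 went from 312 ± 6.24 to 916 ± 12 CPM (1.55 ± 0.04) and MCM4 rose by 1.22 ± 0.04. Of 27 ribosome biogenesis and MYC targets 25 rose and 0 fell (0.66, 4.5e-09; p = 0.22 with an estimated correlation). TFRC, the transferrin receptor, went from 73.8 ± 5.95 to 250 ± 0.442 CPM (1.76 ± 0.06), and the mitochondrial chaperones HSPE1 and HSPD1 rose by 1.36 ± 0.05 and 1.02 ± 0.04. Sterol synthesis genes had 20 of 21 higher and 1 lower (0.56, 8.8e-07; p = 0.091 with an estimated correlation), with SQLE at 0.99 ± 0.04 and IDI1 at 1.04 ± 0.04. Heat shock and immediate early genes had 9 of 14 higher and 3 lower (0.91, 0.011; p = 0.40 with an estimated correlation). The chaperones HSPA8, HSPH1 and HSPA1B rose by 1.74 ± 0.05, 1.52 ± 0.05 and 1.55 ± 0.05, the last with a near-identical copy.

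Granulocyte and MLL-fusion genes were lower in ERDD, and monocyte genes went both ways. Granulocyte genes had 1 of 11 higher and 9 lower (median -0.59, adjusted p = 0.0037; adjusted p = 0.25 with an estimated correlation). The G-CSF receptor CSF3R was at -1.06 ± 0.04, CTSG at -1.12 ± 0.07 and azurocidin, AZU1, at -0.73 ± 0.06. Monocyte genes had 13 of 36 higher and 16 lower (-0.05, 0.54). S100A9 went from 114 ± 11.6 to 21.2 ± 0.574 CPM (-2.40 ± 0.07), and the factors CEBPB and CEBPD changed by -1.44 ± 0.06 and -1.18 ± 0.05. Cathepsin L, CTSL, rose by 1.21 ± 0.05. MLL-fusion genes had 4 of 27 higher and 14 lower (-0.20, 0.042; p = 0.55 with an estimated correlation). MYC went from 356 ± 10.6 to 224 ± 5.76 CPM (-0.67 ± 0.04), and LMO2 was at -0.77 ± 0.04. NF-kB targets had 6 of 21 higher and 10 lower (-0.31, 0.20), with NFKB2 at -1.21 ± 0.06 and TNFAIP3 at -1.46 ± 0.11. Apoptosis genes had 15 of 29 higher and 11 lower (median 0.16, mean -0.07, 0.79), with the cell cycle inhibitor CDKN1A from 75.7 ± 3.12 to 186 ± 3.58 CPM (1.30 ± 0.05) and SESN2 at -1.70 ± 0.05. LSC17 had 2 of 10 higher and 4 lower (-0.02, 0.79) and demethylases 6 of 19 each way (-0.04, 0.72), with KDM6B at -1.45 ± 0.07. Other lineages had 2 of 10 higher and 1 lower (-0.01, 0.79), with the platelet integrin ITGA2B at -1.67 ± 0.14.

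The comparison called 9415 genes, 68.1% of those tested, 4807 higher and 4608 lower, of which 845 changed at least 2-fold (316 higher, 529 lower). PHF8 RNA differed too (-0.95 ± 0.07, adjusted p = 9.2e-06).

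**Figure D3:**
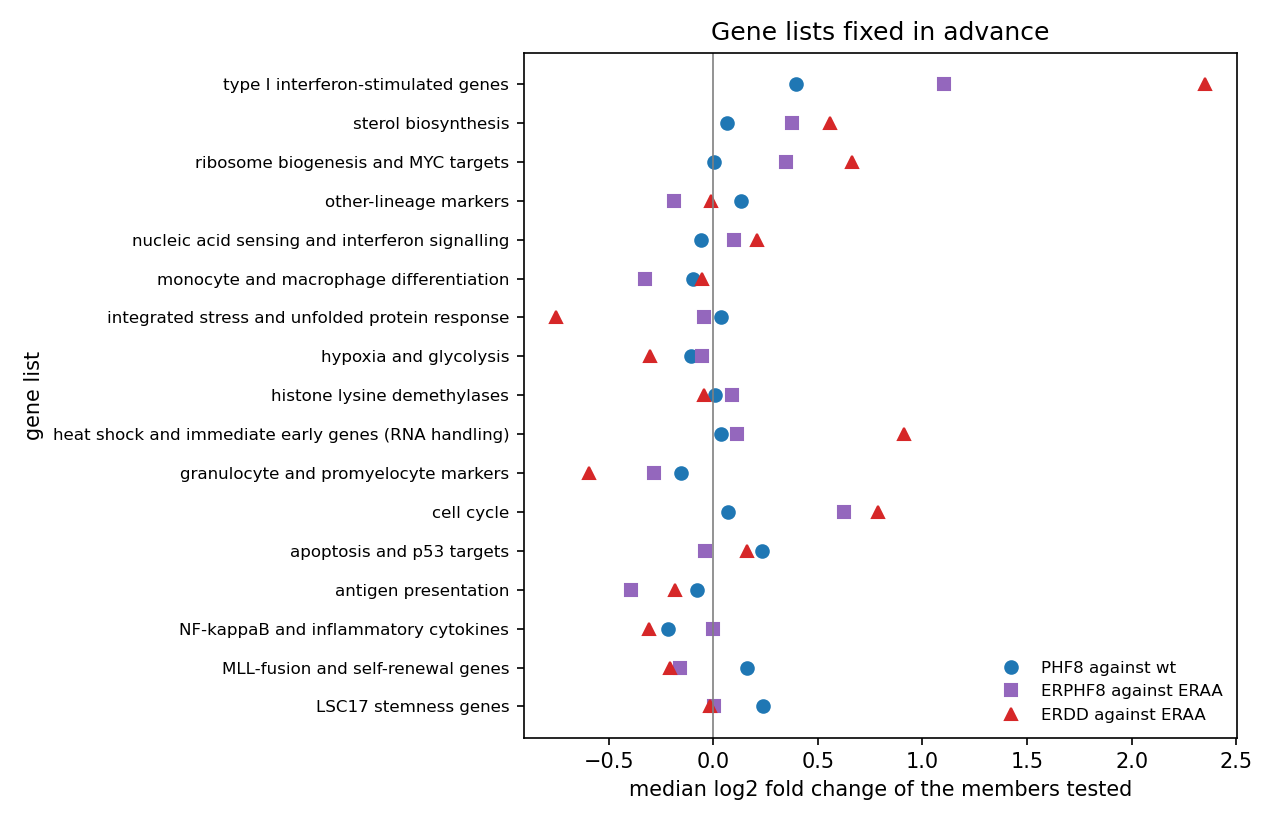
Median log2 fold change of each of the 17 gene lists in PHF8 against wt, ERPHF8 against ERAA and ERDD against ERAA; each point is 1 list in 1 comparison. The interferon-stimulated list lies at 0.39, 1.10 and 2.35 and the cell cycle list at 0.07, 0.62 and 0.79.

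ERPHF8 against ERAA set the line whose label names PHF8 against PHF8AA, with 4-OHT named for ERAA alone, so the form and the drug cannot be separated here. Interferon-stimulated genes led again at a smaller size. IFI44L stood at 31.3 ± 0.742 against 2.46 ± 0.245 CPM (log2 change 3.43 ± 0.07, adjusted p = 1.4e-07) and IFI27 at 12.5 ± 0.905 against 1.41 ± 0.182 (2.77 ± 0.09). MX1 stood at 106 ± 0.92 against 17.6 ± 0.0336 (2.57 ± 0.04) and IFI44 at 23.5 ± 0.443 against 3.93 ± 0.167 (2.44 ± 0.06). All 45 of the list were higher and 0 lower (median 1.10, 9.4e-24; adjusted p = 0.019 with an estimated correlation). ASS1 was lower (126 ± 5 against 473 ± 38.4 CPM, -1.90 ± 0.06), as were the adhesion molecule CADM1 (-1.84 ± 0.14), the potassium channel KCNK15 (-1.84 ± 0.20), which overlaps RIMS4, and the kinase RPS6KA2 (-1.79 ± 0.10), which overlaps another gene. In all 7436 genes changed, 4103 higher and 3333 lower, 196 of them at least 2-fold (85 higher, 111 lower); without ERPHF8 library 2 the count was 4855. The difference of PHF8 in ERPHF8 against ERAA was -0.17 ± 0.07 (0.063). It was -0.07 without ERAA library 1 and -0.27 without ERAA library 2, which held 2305 and 1995 CPM of PHF8. With 1 ERAA library left its spread is not measured, so no call is read from these 2 values.

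Cell cycle genes were all higher in ERPHF8 than in ERAA, 33 of 33 (median 0.62, adjusted p = 9.0e-17; adjusted p = 0.066 with an estimated correlation), with MCM4 at 1.02 ± 0.04 and BUB1, of the spindle checkpoint, at 0.87 ± 0.04. Ribosome biogenesis had 22 of 27 higher and 0 lower (0.35, 7.2e-07; p = 0.26 with an estimated correlation), with TFRC at 1.11 ± 0.06. Sterol genes had 19 of 21 higher and 0 lower (0.38, 7.2e-07; p = 0.066 with an estimated correlation), with IDI1 at 0.82 ± 0.04. Antigen presentation was lower, 3 of 26 higher and 16 lower (3 and 17 adjusted over the list alone; -0.39, 3.7e-05; p = 0.29 with an estimated correlation). CD74 went from 572 ± 41.8 to 318 ± 0.348 CPM (-0.84 ± 0.05), and HLA-E and HLA-DRA were at -0.72 ± 0.05 and -0.67 ± 0.05. Monocyte genes were lower too, 3 of 36 higher and 21 lower (4 and 23 adjusted over the list alone; -0.33, 3.7e-05; p = 0.26 with an estimated correlation). Apolipoprotein E, APOE, was at -1.27 ± 0.07 and CEBPA at -0.52 ± 0.04. Granulocyte genes were lower as well, 2 of 11 higher and 8 lower (2 and 9 adjusted over the list alone; -0.28, 0.010; p = 0.28 with an estimated correlation), with neutrophil elastase, ELANE, at -0.58 ± 0.05.

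The other lists were not called between ERPHF8 and ERAA. Sensing genes had 14 of 28 higher and 7 lower (0.10, adjusted p = 0.33), with IFI16 at 0.71 ± 0.05 and ADAR at 0.57 ± 0.05. MLL-fusion genes had 5 of 27 higher and 13 lower (5 and 14 adjusted over the list alone; -0.16, 0.072), with HOXA7 at -1.07 ± 0.10 and MYC at -0.33 ± 0.04. The stress response had 8 of 22 higher and 10 lower (9 and 10 adjusted over the list alone; -0.05, 0.41), with ASNS at -1.20 ± 0.04 and PHGDH at -0.99 ± 0.04. NF-kB targets had 5 of 21 higher and 8 lower (-0.00, 0.38), with ICAM1 at -1.34 ± 0.09. Heat shock genes had 7 of 14 higher and 5 lower (0.11, 0.51), with HSP90AA1 at 0.84 ± 0.04 and JUN at -0.96 ± 0.06. Hypoxia genes had 8 of 21 higher and 7 lower (-0.05, 0.66), with LDHA at 0.62 ± 0.04 and VEGFA at -0.95 ± 0.07. Apoptosis genes had 6 of 29 higher and 8 lower (-0.04, 0.41), LSC17 3 of 10 higher and 2 lower (0.00, 0.86), demethylases 5 of 19 higher and 2 lower (0.09, 0.69) and other lineages 2 of 10 higher and 3 lower (-0.19, 0.53).

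ERDD against ERPHF8 is likewise also a comparison with and without the 4-OHT tag. The interferon-stimulated genes were higher in ERDD in all 45 cases (median 1.37, adjusted p = 1.1e-32; adjusted p = 0.012 with an estimated correlation). IFI27 was at 3.23 ± 0.09, IFI44L at 2.45 ± 0.07, IFIT1 at 2.37 ± 0.08 and MX1 at 2.10 ± 0.04. DLX3, a homeobox gene (chromosome 17, 49990005 to 49995224), rose from 1.83 ± 0.707 to 11.3 ± 0.0426 CPM (2.38 ± 0.18, 5.9e-05). INHBE (-2.72 ± 0.10), MS4A4E (-2.67 ± 0.29), TBC1D30, a Rab GTPase-activating protein (-2.60 ± 0.08), and SULF2 (-2.57 ± 0.05) were lowest relative to ERPHF8. PHF8 RNA was lower in ERDD (-0.78 ± 0.07, 9.4e-05). In all 7305 genes differed, 3428 higher and 3877 lower, 338 of them at least 2-fold (143 higher, 195 lower); the count was 4524 without ERDD library 1, 4310 without ERDD library 2 and 4458 without ERPHF8 library 2.

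Several lists rose in ERDD against ERPHF8, each lost with an estimated correlation. Sensing genes had 13 of 28 higher and 3 lower (0.12, adjusted p = 0.013; adjusted p = 0.50 with an estimated correlation), with DHX58 at 1.31 ± 0.06 and the adaptor MYD88 at 0.88 ± 0.04. Antigen presentation had 11 of 26 higher and 1 lower (0.17, 0.0011; p = 0.36 with an estimated correlation), with TAP1 at 0.89 ± 0.04 and PSMB8 at 0.54 ± 0.06. Heat shock genes had 10 of 14 higher and 1 lower (10 and 2 adjusted over the list alone; 0.61, 7.0e-05; p = 0.24 with an estimated correlation), with BAG3 at 0.85 ± 0.05. Ribosome biogenesis had 20 of 27 higher and 0 lower (22 and 0 adjusted over the list alone; 0.27, 2.5e-07; p = 0.24 with an estimated correlation) and cell cycle genes 17 of 33 higher and 2 lower (0.12, 0.0023; p = 0.29 with an estimated correlation). Sterol genes had 13 of 21 higher and 2 lower (13 and 3 adjusted over the list alone; 0.22, 0.0044; p = 0.24 with an estimated correlation), although FDPS was at -0.45 ± 0.04. Hypoxia genes fell, 2 of 21 higher and 12 lower (2 and 13 adjusted over the list alone; -0.21, 0.0015; p = 0.24 with an estimated correlation), with ALDOC at -1.44 ± 0.05. Granulocyte genes fell too, 1 of 11 higher and 7 lower (-0.31, 0.013; p = 0.29 with an estimated correlation), with myeloperoxidase, MPO, at -0.93 ± 0.10.

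Monocyte genes went both ways between ERDD and ERPHF8, 16 of 36 higher and 12 lower (0.08, adjusted p = 0.13). CSF1R, the M-CSF receptor, was at 293 ± 5.17 against 152 ± 2.83 CPM (0.94 ± 0.04), with S100A9 at -1.63 ± 0.07. The stress response had 8 of 22 higher and 13 lower (-0.61, 0.057), with CHAC1 at -2.52 ± 0.06 and DDIT4 at -2.34 ± 0.04. MLL-fusion genes had 7 of 27 higher and 12 lower (7 and 13 adjusted over the list alone; -0.21, 0.13), with RUNX2 at -0.70 ± 0.08. NF-kB targets had 4 of 21 higher and 9 lower (-0.18, 0.36), with TNFAIP3 at -1.0 ± 0.11. Apoptosis genes had 11 of 29 higher and 8 lower (12 and 10 adjusted over the list alone; 0.03, 0.41), with CDKN1A at 1.05 ± 0.05 and SESN2 at -1.66 ± 0.05. Demethylases had 2 of 19 higher and 7 lower (-0.08, 0.13), with KDM6B at -0.92 ± 0.07, LSC17 2 of 10 higher and 1 lower (-0.08, 0.77) and other lineages 4 of 10 higher and 2 lower (0.22, 0.16).

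The experiments were set side by side over the 13504 genes tested in both, with no library shared. Fold changes of PHF8 against wt and of ERPHF8 against ERAA had a Pearson correlation of 0.154 and a Spearman correlation of 0.152 across genes, which are not independent replicates. Both called 578 genes higher, where independent lists would share 517, and 457 lower, where they would share 269 (Fisher's exact test, 0.00073 for the higher and 1.6e-38 for the lower genes). Opposite calls, 570 here, are given in this paragraph without the number that independent lists would have, so they cannot be weighed against the shared ones. These comparisons also share a trend on GC content: in ERPHF8 against ERAA genes called higher had a median of 45.3% and those called lower 55.0%, beside 44.5% and 54.8% in PHF8 against wt. With GC and span trends removed from both, the Pearson correlation was 0.0813, and 544 higher calls were shared against 518 (0.14) and 398 lower calls against 297 (5.3e-12). For PHF8 against F279S and ERDD against ERAA the correlations were 0.121 and 0.0762, with 638 shared higher calls against 574, 465 shared lower calls against 353 and 683 in opposite directions (0.00046 and 1.1e-13). Among genes of at least 5 CPM the excess of higher calls did not pass, 524 against 493 (0.066), while with trends removed it did, 668 against 569 (4.6e-08).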

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

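Chosen after their results were seen were the tests of differences between the library pairs, the other splits of the libraries, the PHF8 ratio, the share of changed genes, the smallest list median over the scalings, both tests of mixed material, the calls kept with GC and span trends removed, the GC slopes by line and the slopes at equal depth.

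Libraries 1 and 2 differed from 3 and 4 in the size of many changes. A test of the difference between the pairs called 4179 genes for PHF8 against wt, 123 for F279S against wt and 2985 for PHF8 against F279S. Medians of 8 list comparisons also differed between the pairs with an estimated correlation. In PHF8 against wt these were ribosome biogenesis (-0.26 in libraries 1 and 2, 0.28 in 3 and 4, adjusted p = 0.0014) and sterol synthesis (0.15 and -0.19, 0.016). In F279S against wt they were the interferon-stimulated list (0.43 and 0.08, 1.4e-04), ribosome biogenesis (-0.052 and 0.03, 0.037), sterol synthesis (0.12 and -0.11, 0.0010) and hypoxia (-0.16 and -0.02, 0.0038). In PHF8 against F279S they were the interferon-stimulated list (-0.071 and 0.30, 0.0086) and ribosome biogenesis (-0.18 and 0.24, 0.0016). Among the interferon-stimulated genes in F279S against wt, MX1 changed by 1.43 and -0.07 in the pairs and IRF7 by 1.06 and 0.07.

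A sample stood far from the others of its group in 2 of 123 groups of 4 values. Chance gives about 1 in 20 where the 4 values are alike, but here libraries 1 and 2 stood apart from 3 and 4. That rate therefore need not hold, and a low number of flags does not show that no library stood apart. The total of wt library 3 was 42.3 M reads, beside 19.4 to 20.8 M in the others of its line. PGR in F279S library 1 was 0.476 CPM, beside 0.854 to 0.915 in the others. IFNB1, which was too low to test, had 9 reads over the ERDD libraries, beside 2 over ERAA and 3 over ERPHF8.

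The 8 libraries of a comparison in the first experiment can be parted into 4 and 4 in 35 ways. For PHF8 against wt 1 of the 35, the real one, gave as many as its 2874 genes, and the highest other gave 26. For PHF8 against F279S this was 1 of 35 as well, with 2750 genes against 90. Both counts argue against a chance parting of like libraries, with the smallest share that 35 splits can give. They cannot exclude a chance difference between cultures, since all libraries of a line may come from 1 culture. Of the 2 genes called for F279S against wt, PHF8 was raised by the design, so chance is a question for ACPP alone. The share of splits was 2 of 35, so chance cannot be excluded by this count. The other of the 2 splits, libraries 1 and 2 from 3 and 4, gave 8411 genes against the real 2, which points to a structure of the samples, and the splits besides these gave 0. With the pair of libraries as a factor the real split gave 298 and the splits that do not follow the pairs 0. Of the 8 splits that part all 4 numbers, too few for a share under 0.05, the highest other gave 1, 0 and 0 genes by limma in PHF8 against wt, F279S against wt and PHF8 against F279S. With the pair as a factor PHF8 against wt gave 5595, and the highest other, PHF8 libraries 1 and 2 with wt libraries 3 and 4 against the rest, 324. Without the pair as a factor, the splits along the pairs were the highest others in all 3 comparisons.

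Interferon-stimulated genes were higher in ERDD than in ERPHF8 and in ERPHF8 than in ERAA, with medians of 1.37 and 1.10. More PHF8 RNA in the lines with more of these transcripts is argued against, since the ratio of PHF8 RNA in ERDD to ERAA was 0.516. PHF8 RNA ran in the opposite order, at 1109 CPM in ERDD, 1906 in ERPHF8 and 2150 in ERAA. A lower level of PHF8 RNA therefore cannot be told apart from the form of PHF8, and stays open. The scaling of the libraries is argued against too, since the smallest list median under median-ratio scaling, TMM scaling or the removal of GC and span trends was 1.07. A broader difference in the state of the cultures cannot be told apart from the form of PHF8, since 68.1% of all tested genes differed between ERDD and ERAA and each line may stand for 1 set of cultures. For ERPHF8 the 4-OHT tag is a further open difference, and the form of PHF8 that the labels name stays open as an untested biological explanation.

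The interferon-stimulated list stood higher over wt in F279S libraries 1 and 2 than in 3 and 4, with a median difference of 0.44. RNA of the PHF8 line mixed into libraries 1 and 2 is argued against: 249 markers of that line reached a median share of 1.95% of their PHF8-line level (interquartile range -6.54 to 13.1%), whereas 37 interferon-stimulated genes reached 86.3%. Reads of the ERDD libraries are argued against by ESR1, whose share of its ERDD level was 0.0841%, from 18 reads where the list's share of 3.53% needs 196. The 95% exact Poisson interval of that share was -0.0577 to 0.286%, counting error only. Earlier versions of this test, on 7 and 11 markers, gave median shares of 1.02 and 0.0829%. The 7 markers did not lie far enough below the list's share for the limit used, so that version could not decide. A GC or span trend is argued against, as the difference was 0.45 with trends removed. A difference between the cultures or preparations of the pairs remains open, as no label tells the pairs apart, and no biological explanation was tested.

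Genes higher in PHF8 than in wt had longer spans and a lower GC content than those lower. GC and span trends of the libraries as the cause of the changed genes are argued against, since 2151 of the 2764 calls with a known GC content kept their call and direction with the trends removed, among 2885 calls. Depth as the whole cause is argued against: with line and depth fitted together over 12 libraries, the slopes of PHF8 and wt still differed at equal depth, by -0.118 ± 0.0163 (SE) for GC (log2 per 10 percentage points), beside -0.107 without depth, and by 0.0289 ± 0.00921 for span (log2 per doubling), beside 0.0366; depth itself was related to both slopes in that fit (p = 0.018 and 0.0054), and with lines not told apart GC slope and depth had a Spearman correlation of 0.266 (permutation p = 0.405, approximate SE 0.333). A GC bias from the preparation of the PHF8 libraries cannot be told apart from a change in the cells. GC slopes differed between the lines, with PHF8 at -0.103 to -0.0378 and wt at -0.00433 to 0.0685. An exact permutation test, two-sided, gave p = 0.0286, the smallest that 4 against 4 libraries can give. That test exchanged libraries without regard to their pairs. The added PHF8 itself, named by the design, is an untested biological explanation.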

How the results depend on the processing

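Chosen only after the data were seen were TMM scaling, both other pseudocounts, log2(RPKM + 0.1), voom, averaged pairs, genes overlapping no other, removed GC and span trends, the crossed pairing and the correlations without the interferon-stimulated list or with trends removed. DESeq2 was planned and not run, voom on the recovered reads taking its place, and scaling by library total is the deposited one.

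A value counts as reversed where its direction turned and it passed the threshold in either setting. Of 6497 alternative values of named genes outside the leaving out of libraries, 6266 kept their side of the threshold, 55 lost it, 172 gained it and 4 reversed, and 11 others changed sign without passing. With single libraries left out, 2527 of 2608 kept it, 76 lost and 5 gained it, and 13 changed sign without passing. Of 867 list values 751 kept their side, 63 lost it (33 of them with an estimated correlation), 48 gained it and 5 reversed in the direction of the test; the list median changed sign in 45, over 29 lists and comparisons. Of 97 alternative counts 68 stayed within 1.5 times. The genes that reversed were past the threshold in the alternative alone: TFRC in libraries 3 and 4 alone (0.31 in PHF8 against wt, 0.19 in PHF8 against F279S) and ODC1 in libraries 1 and 2 alone (-0.30 and -0.22). CR1 was also not called with voom or log2(RPKM + 0.1), nor SLC2A3 in PHF8 against wt with voom. Calls lost without 1 library were, for PHF8 against wt, CR1, CSF3R, DUSP1, HSPB1, IRF3, MCM5, PSAT1 and SLC2A3; for PHF8 against F279S, CR1, FOSB, FOXM1, MCM3, NGFRAP1, PRTN3 and SOCS3; and in the ER lines LAPTM4B, NYNRIN and NGFRAP1. Where a group is left with 1 library, that library is assumed to vary like the other groups. The cause was not tested for any of these or for the counts below, except where fewer genes or libraries entered.

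Counts are given in the order PHF8 against wt, F279S against wt, PHF8 against F279S. With the replicate number as a block they were 5670, 298 and 5620, and all 2874 genes called in PHF8 against wt without it kept their call. With the library pair as a factor they were 5595, 298 and 5565, in libraries 1 and 2 alone 7025, 1918 and 7357, in libraries 3 and 4 alone 5833, 12 and 4867, with pairs averaged 1775, 1 and 1594, and with GC and span trends removed under the block 5660, 358 and 5452. For F279S against wt, removing the trends without a block gave 5 and log2(RPKM + 0.1) gave 4. At least 2-fold were 450, 1 and 391 genes, and in the ER lines 845 for ERDD against ERAA, 196 for ERPHF8 against ERAA and 338 for ERDD against ERPHF8. Genes overlapping no other gave 5711, 4645 and 4432 in the ER lines, where fewer genes were tested. voom on the recovered reads called 2828, 2, 2862, 9384, 7431 and 7279. Leaving out each library in turn gave 2215 to 2632 genes for PHF8 against wt, 2 for F279S against wt in each case, 2076 to 2461 for PHF8 against F279S, 7481 to 10162 for ERDD against ERAA, 4855 (without ERPHF8 2) to 8742 for ERPHF8 against ERAA and 4310 (without ERDD 2) to 5226 for ERDD against ERPHF8, with 4524 without ERDD 1 and 4458 without ERPHF8 2.

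In the ER lines same-numbered libraries did not deviate together (correlations of -0.34 to 0.10, 2 of 6 best with their own number), and the block gave 9068, 6900 and 6801 genes. A crossed pairing of ERAA and ERPHF8 gave 8077. The block changed the call of 3 lists: MLL-fusion and monocyte genes in PHF8 against F279S (0.038 to 0.097 each) and hypoxia genes in F279S against wt (0.58 to 0.015); it changed no other list's call.

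For the interferon-stimulated list, PHF8 against wt (median 0.39) had adjusted p = 0.62 with an estimated correlation. F279S against wt (0.24) had 0.21 with it, 0.066 by fry and 0.14 in libraries 3 and 4 alone (0.076). PHF8 against F279S had 0.0024 in libraries 3 and 4 alone (0.30). Lists that reversed past the threshold were ribosome biogenesis in libraries 3 and 4 alone (0.28 in PHF8 against wt, adjusted p = 2.0e-05; 0.24 in PHF8 against F279S, 5.1e-05), sterol genes there in F279S against wt (-0.11, 3.0e-05), and by fry, which weighs the mean, demethylases in F279S against wt (median -0.068, 0.00028, with PHF8 itself a member) and apoptosis genes in ERDD against ERAA (0.16, 0.0047). The correlation of PHF8 against wt with ERPHF8 against ERAA fell from 0.154 to 0.0813 with GC and span trends removed, where the excess of shared higher calls lost its call (0.14), and was 0.144 to 0.165 otherwise. That of PHF8 against F279S with ERDD against ERAA was 0.103 to 0.129 throughout, and its excess of shared higher calls lost its call among genes of at least 5 CPM (0.066). Depth limits the interferon genes, which lay near or below the floor of 0.0582 to 0.164 CPM.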

Other observations

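All 12 gene families below, and the test of an ATF4 response, were chosen after values had been seen. No family had an adjusted p below 0.05 with an estimated correlation in any comparison, so each is described by its members alone.

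Of 79 genes of cytosolic ribosomal proteins, 75 were lower and 1 higher in ERDD than in ERAA (median log2 change -0.52; adjusted p = 0.43 with an estimated correlation), and 74 lower and 1 higher in ERPHF8 than in ERAA (-0.32). Between ERDD and ERPHF8, 44 were lower (-0.20), with 26 under median-ratio scaling and 69 with GC and span trends removed. Proteasome subunits went the other way, with 42 of 47 higher and 1 lower in ERDD than in ERAA (0.45). So did mitochondrial ribosomal proteins, 54 of 77 higher and 7 lower (0.26), and complex I subunits of the respiratory chain, 29 of 37 higher and 2 lower (0.30). In ERPHF8 against ERAA these medians were 0.19, 0.16 and 0.14, and in ERDD against ERPHF8 0.28, 0.14 and 0.19. Of 418 ZNF-named zinc finger genes 200 were lower and 50 higher in ERDD than in ERAA (-0.19) and 220 lower and 23 higher than in ERPHF8 (-0.25), whereas 44 were lower and 97 higher in ERPHF8 than in ERAA (0.06). Guanylate-binding proteins, interferon-induced GTPases outside the list used here, were all higher in PHF8 than in wt (4 of 4, 1.36) and in ERDD than in ERAA (5 of 5, 0.55) and ERPHF8 (5 of 5, 0.40). They had 2 of 5 higher in ERPHF8 against ERAA (0.15), 1 of 4 in PHF8 against F279S (0.67) and 0 of 4 in F279S against wt (0.50), the last 2 comparisons having 4 and 1 with the replicate number as a block and 0 each with pairs averaged. Both scalings tried left the directions of these medians in place, but a scaling cannot remove a trend on GC content or span. In ERDD against ERPHF8, genes called higher had medians of 53.1% GC and 21.9 kb, and those called lower 45.5% and 47.8 kb. In ERPHF8 against ERAA the higher had 45.3% and 45.1 kb and the lower 55.0% and 20.6 kb. In ERDD against ERAA the GC medians were closer, 48.4% and 50.7%. Values with these trends removed are not given here for the zinc finger genes.

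The protocadherin clusters on chromosome 5, adhesion genes that share exons and whose overlapping spans share reads, were called mostly together within a cluster. All 22 gamma members were higher in PHF8 than in wt (0.74; adjusted p = 0.51 with an estimated correlation), and 7 of 10 beta members (0.42, 0.084), which overlap less. Gamma members had 0 of 22 called in F279S against wt (0.32) and in PHF8 against F279S (0.41), and 22 of 22 higher in each with the replicate number as a block. With each pair of libraries averaged and the pair as a block, 0 were called in F279S against wt and 20 in PHF8 against F279S. In the ER lines all 22 were higher in ERDD than in ERAA (0.28) and ERPHF8 (0.47), but lower in ERPHF8 than in ERAA (-0.19). Beta members had 6 of 10 higher in PHF8 against F279S (0.37), and 5 of 11 lower and 1 higher in ERDD against ERAA (-0.35). All 15 alpha members were lower in PHF8 than in F279S (-0.42, 0.55) and in ERPHF8 than in ERAA (-0.54), and higher in ERDD than in ERPHF8 (0.61). In the 3 other comparisons 0 alpha members were called, but with GC and span trends removed 8 of 15 were lower in PHF8 than in wt (-0.31). With pairs averaged 0 alpha members were called in PHF8 against F279S, and 1 beta member in PHF8 against each of wt and F279S. Both scalings tried left the directions of these medians in place as well. Members of a cluster are not separate measurements, since reads of a shared span count for each.

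Of 7 genes of serine and one-carbon synthesis, 7 were lower in ERDD than in ERAA (median -1.51; adjusted p = 0.19 with an estimated correlation) and 6 in ERPHF8 than in ERAA (-0.76). A hypothesis is that an amino acid response under ATF4, a factor that drives these genes and the cytosolic aminoacyl-tRNA synthetases, differs between the lines. If so, the cytosolic synthetases would lie below their mitochondrial counterparts. The cytosolic genes had a median of -0.58 (14 of 20 lower, 5 higher) and the mitochondrial ones 0.14 (8 of 17 higher, 1 lower), a difference of -0.72, with adjusted p = 0.21 for each family with an estimated correlation. This is consistent with the hypothesis, which was formed and tested on the same libraries, and nothing here tells whether a form of PHF8 or the culture conditions could set such a response. In PHF8 against wt the serine family went the other way, 3 of 7 higher and 0 lower (0.29), 5 with the replicate number as a block and 4 with GC and span trends removed.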
